A study of Mus musculus with 4 samples.

How the data were processed

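Hindlimb muscle of male C57Bl/6J mice was irradiated on one side with 3 fractions of 8.2 Gy X-rays while the rest of the body was shielded, per the labels' protocols. Limbs were dissociated with collagenase and dispase, treated with a red cell lysis buffer, pooled from 3 limbs per group, and sorted as live (SYTOX-negative), Hoechst-stained mononucleated cells, with a minimum of 10,000 sorted cells per group. The 3' version 3 chemistry of 10x Genomics and a NextSeq 500 instrument were used, with 10,000 reads per cell planned. The deposited matrices held 1471, 2763, 1822 and 1030 barcodes in the control and irradiated libraries at 24 hours and then at 56 days, fewer than the stated number of sorted cells. Reads were aligned to mm10 and counted by the authors with Cell Ranger 5.0.0, per the submitters' processing notes and the file headers, and the deposited matrices hold UMI counts for 32285 genes in barcodes that had already been filtered, with a lowest total of 500 UMIs.

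Raw UMI counts were used as deposited for all sums and ratios. Groups were taken from the sample titles, with 1 library per group. No test between groups was made and no p-value was computed. The comparisons were IR over CON at 24 hours, IR over CON at 56 days, and CON 56 days over CON 24 hours. The filters, lists, classes and thresholds below were set before the data were examined unless a later choice is named.

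Barcodes with at least 200 genes, at least 500 UMIs and at most 20% mitochondrial UMIs were kept. This removed 331 barcodes under the gene limit and 361 over the mitochondrial limit, with overlap, and left 6544. Scrublet scoring in scanpy at an expected doublet rate of 0.05 marked 24 of them (0.367%), which were removed, leaving 6520 cells. This is far under the rate set, so the caller was taken not to have worked on these libraries, and mixed cells may remain. Ambient RNA was not removed.

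Counts were normalised to 10000 per cell and log-transformed for clustering only. Clustering used 2000 variable genes among those found in at least 3 cells, 30 principal components, 15 neighbours and the Leiden method at resolution 1.0 with seed 1, on all libraries together without batch correction. A cluster was named from 20 fixed marker lists where at least 3 markers and 40% of a list were enriched 2-fold over other cells and found in 10% of its cells. The 40% was chosen after the clusters were seen. A cluster with low UMIs and no marker of its closest class among its 10 genes of highest fold stayed unnamed. So did a cluster with more markers of another class among those genes. It is not recorded whether these rules preceded the clusters. The low-UMI rule left a cluster of 513 cells unnamed although 5 of 9 endothelial markers were enriched in it. Classes are called by resemblance only, because no protein or position was measured. Sizes of clusters within the endothelial-like class were not given by group, because genes that define them differed between the groups, and only the cluster with most cells is named.

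UMIs were summed over the cells of a class in each library and scaled to the class total (CPM). A ratio carries an exact conditional binomial interval for 2 Poisson counts, a level an exact Poisson interval and a share an exact binomial interval, all at 95% and for counting error only. Log2 ratios used a prior count of 0.5. Genes with at least 20 summed UMIs over both libraries counted as measured, in classes with at least 50 cells in both libraries. Classes with at least 25 cells (FAPs, satellite-like and macrophage-like cells, and myofibre-like barcodes at 56 days) were added after the cell numbers were seen. Neutrophil-like cells at 24 hours and erythroid-like cells at 56 days also met this limit, but their expression is not described. Where one library had 0 UMIs, the least fold is given against a floor of 3 UMIs.

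Fixed gene lists were summarised by the median log2 ratio of measured members, an order-statistic interval (95%, or the range of under 6 members), the percentile of that median among 10000 random lists matched in 20 expression bins, and the number of members at least 1.5-fold higher or lower. The 27 lists were written before the files were opened. Named genes follow a fixed rule for the 4 classes with the most cells in the smaller of their libraries. In each, the 3 genes furthest higher and the 3 furthest lower were ranked by the bound of the ratio interval nearest to 1. The ranking left out mitochondrially encoded, ribosomal protein, haemoglobin, sex-linked, predicted and immune receptor genes, and markers of other classes. From each list described, 2 to 4 leading members were added, as were Cdkn1a, Mdm2, Ccng1 and Phlda3 in every class described. A leading list member that this rule would add is not reported here. Symbols Ccl21a, Mx1, Ctgf and Figf on these lists were not matched, and 40 symbols repeated in the gene table were kept apart by Ensembl identifier. Cycling cells were those with at least 1 UMI of Mki67 or Top2a after each cell was thinned to 1000 UMIs.

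Alternatives covered no filter on cells, at most 10% mitochondrial UMIs, doublets kept, Leiden resolutions 0.5 and 2.0, cells classed one by one by marker score, scaling by the median ratio, by edgeR's TMM factors or without mitochondrial and haemoglobin genes, minimum sums of 50 UMIs and 1 UMI, a prior count of 5, each cell weighted equally, and thinning to 1000 UMIs (500 for cycling cells). Added after the data were seen were removal of the top 5% of doublet scores per library, leaving out cells of other classes with at least 5 UMIs of 9 endothelial markers, the larger B-like cluster alone, shares within stromal or blood classes, and a set of clock genes. Gene positions came from GENCODE M21 on GRCm38 (mm10), matched by Ensembl identifier.

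The ratio step was tested on simulated data, in which Poisson counts were drawn from the mean profile of a class at the real depths and 200 genes were changed by known folds. Intervals held the true ratio for 95.8% of 10842 genes of the endothelial-like class at 24 hours. Simulated 2-fold differences had an interval past 1 in 85.6% of genes there, 83.7% for endothelial-like cells at 56 days (10050 genes), 61.9% for B-like cells at 24 hours (5900 genes) and 52.1% for FAPs at 56 days (6359 genes). A 20-gene list made 1.5-fold higher reached percentile 100.0 in all of them. The counts were drawn under the model that the intervals assume, without clumping in single cells or differences between libraries. These rates therefore check the calculation only and need not hold for the real libraries.

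Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16 (scaling factors only). Trajectories, velocity, ligand and receptor scores and copy number were not analysed here.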

Results

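Mouse hindlimb muscle cells were profiled by single-cell RNA sequencing, with 1 library per group: shielded control limbs (CON) and irradiated limbs (IR) taken 24 hours after the last of 3 X-ray fractions of 8.2 Gy or 56 days after irradiation. The control was the other limb of the irradiated male C57Bl/6J mice, which were 5 weeks old at irradiation. Cells from 3 limbs were pooled before live, nucleated cells were sorted. The deposited matrices held 1471, 2763, 1822 and 1030 barcodes in the control and irradiated libraries at 24 hours and then at 56 days (the order used for each group of 4 values), with 6339993, 10121978, 8842963 and 4715202 unique molecular identifiers (UMIs). After filtering, 1332, 2531, 1692 and 965 cells were kept, with medians of 3455, 3056, 3622 and 3453 UMIs and 1415, 1566, 1550.5 and 1600.0 genes per cell. With no replicate libraries, differences between groups were not tested, and each interval in parentheses is a 95% interval unless a list has under 6 measured members, where it is their range. Intervals of levels, shares and ratios cover counting error only, and those of list medians cover the spread among member genes.

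The p53 target Cdkn1a, which encodes the cell cycle inhibitor p21, followed the labels at both times. Over all kept cells, with UMIs scaled to the library or class total (CPM), it had 165.9 CPM (155.7 to 176.5) in the control and 1836 (1809 to 1863) in the irradiated library at 24 hours, against 106.8 (99.97 to 114.0) and 794.9 (769.1 to 821.4) at 56 days. Mdm2, the ubiquitin ligase gene that p53 induces against itself, had 41.2, 185.0, 35.0 and 59.1 CPM in the 4 libraries, and Ccng1, the cyclin G1 gene, had 42.5, 205.7, 34.7 and 66.8. Phlda3, which encodes a repressor of Akt signalling, had 86.9, 443.2, 40.9 and 273.3. The Y-linked gene Ddx3y was present in every library at 80.4, 130.0, 86.1 and 81.0 CPM, and Xist, which marks female cells, had 1, 0, 3 and 0 UMIs. Cdkn1a (ENSMUSG00000023067) lies at chromosome 17, 29090976 to 29100727 of mm10, and Mdm2 (ENSMUSG00000020184) at chromosome 10, 117688875 to 117710758. The others lie at chromosome 11, 40748552 to 40755311 (Ccng1, ENSMUSG00000020326) and chromosome 1, 135766119 to 135769136 (Phlda3, ENSMUSG00000041801).

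Clusters named by fixed markers gave endothelial-like cells as the largest class, with 410, 1307, 664 and 436 cells in the 4 libraries. Stromal and vascular classes (endothelial-like, pericyte or smooth muscle-like, Schwann-like, satellite-like, fibro-adipogenic progenitor-like and tenocyte-like) made up 45.4%, 72.3%, 58.9% and 67.8% of sorted live nucleated cells with at least 500 UMIs and 200 genes. Blood and marrow classes made up 41.3% (38.6 to 44.0), 11.1% (9.94 to 12.4), 29.4% (27.2 to 31.6) and 19.9% (17.4 to 22.6). Clusters left without a name held 6.46%, 9.92%, 9.04% and 7.05% of cells, most of them in a low-UMI cluster led by Lars2 and AY036118. Myofibre-like barcodes numbered 91, 169, 45 and 51 and had few UMIs, so they were treated as fibre debris rather than whole cells.

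**Figure D1:**
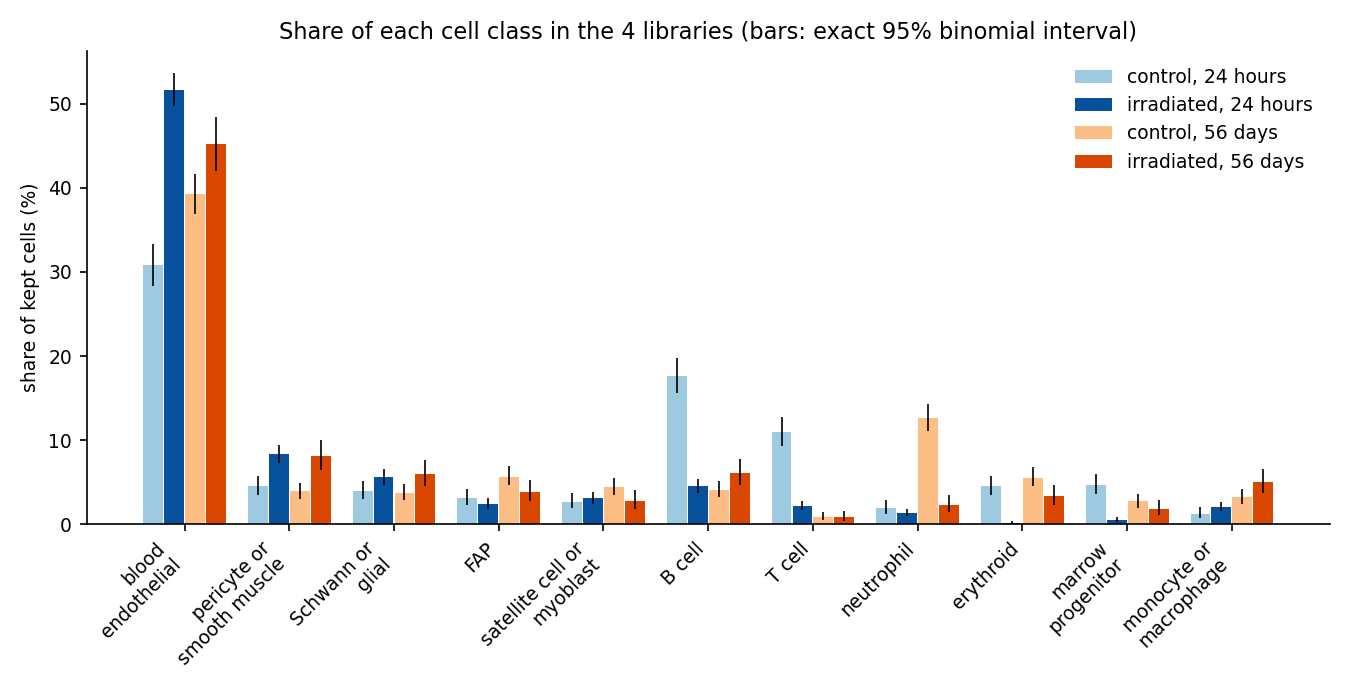
Share of kept cells (%) in each cell class for the 4 libraries. Bars show exact 95% binomial intervals.

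At 24 hours the endothelial-like cells of the irradiated library carried strongly higher p53 targets. Cdkn1a had 541 and 12874 UMIs in the control and irradiated libraries, 318 and 2411 CPM, a ratio of 7.59-fold (6.96 to 8.29). Gdf15, a stress cytokine of the TGF-beta family (ENSMUSG00000038508, chromosome 8, 70629393 to 70632456), was 47.3-fold (29.5 to 81.3) higher, with 17 and 2520 UMIs. Sesn2, an mTORC1 inhibitor gene of the stress response, was 8.86-fold (5.74 to 14.4) higher, Ccng1 6.28-fold (4.92 to 8.13), Mdm2 4.53-fold (3.67 to 5.65) and Phlda3 4.37-fold (3.81 to 5.03). Among p53 targets 23 of 25 members were at least 1.5-fold higher and 0 at least 1.5-fold lower, with a median log2 ratio of 2.05 (1.29 to 2.24), at percentile 100.0 of 10000 random lists matched on expression. The largest differences by the fixed rule of size included Ltc4s, the leukotriene C4 synthase gene (ENSMUSG00000020377, chromosome 11, 50236461 to 50238616), at 27.2-fold (16.9 to 46.8). Ckap2, a gene of the mitotic cytoskeleton (ENSMUSG00000037725, chromosome 8, 22168160 to 22185819), had 2 and 371 UMIs and a ratio of 59.2-fold (16.3 to 490.4). The genes furthest lower included Gnat3, a G protein subunit gene, at 0.08700-fold (0.0289 to 0.221) and the secretoglobin gene Scgb3a1 at 0.173-fold (0.0936 to 0.311). Penk, the proenkephalin gene (ENSMUSG00000045573, chromosome 4, 4133531 to 4138819), had 20 UMIs against 0, at least 20.9-fold lower, and nearly all lay in 1 control cell.

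Interferon-response and antigen-presentation genes were lower in the irradiated endothelial-like cells at 24 hours. One endothelial cluster was led by the interferon genes Ifit1, Ifit2 and Ifit3, so these class ratios include its share. The type I interferon list had a median log2 ratio of -0.46 (-0.80 to -0.21) at percentile 0.0, and 0 of 18 members were at least 1.5-fold higher and 6 at least 1.5-fold lower. Irf7, the interferon regulatory factor gene, was at 0.4704-fold (0.387 to 0.573), the antiviral gene Rsad2 at 0.491-fold (0.4197 to 0.575), Ifit3 at 0.505-fold (0.412 to 0.621) and the ubiquitin-like Isg15 (ENSMUSG00000035692, chromosome 4, 156199424 to 156200818) at 0.588-fold (0.524 to 0.6601). The MHC class I list had a median of -0.45 (-0.55 to -0.24), led by the immunoproteasome genes Psmb9 at 0.594-fold (0.5097 to 0.693) and Psmb8 at 0.641-fold (0.577 to 0.713). Capillary genes were lower too, with a median of -0.52 (-1.42 to -0.29) and 4 of 10 members at least 1.5-fold lower, among them carbonic anhydrase Car4 at 0.285-fold (0.247 to 0.3300), Timp4 at 0.374-fold (0.3503 to 0.4003) and the fatty acid carrier Fabp4 at 0.521-fold (0.515 to 0.527). The adipogenic list had a median of -0.62 (-1.39 to -0.19), with the adipsin gene Cfd at 0.255-fold (0.1495 to 0.432) and the lipid regulator gene Pparg at 0.498-fold (0.403 to 0.617).

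Endothelial activation genes differed in opposite directions at 24 hours. Apln, the apelin gene of sprouting tips, was 4.58-fold (3.05 to 7.17) higher, while the venular genes Lrg1 and Ackr1 were at 0.259-fold (0.215 to 0.312) and 0.334-fold (0.232 to 0.481) and the adhesion gene Vcam1 at 0.3802-fold (0.275 to 0.526), with a list median of -0.35 (-1.39 to 0.49). Gas6, the ligand of the TAM receptors (ENSMUSG00000031451, chromosome 8, 13465374 to 13494490), was 2.599-fold (2.42 to 2.79) higher on 861 and 7014 UMIs, and the growth factor ligand list had a median of 0.28 (-0.60 to 1.06). In the chemokine and cytokine list (median 0.72 (-0.72 to 1.79)), Tnf was 3.56-fold (1.55 to 10.1) higher and Cxcl12 was at 0.635-fold (0.608 to 0.662). The secretory senescence list had a median of 0.28 (-0.27 to 0.74). Among double-strand break repair genes (median 0.27 (-0.06 to 0.83)), Brca2 was 3.25-fold (1.31 to 10.4) and Trp53bp1 2.06-fold (1.33 to 3.31) higher.

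The following endothelial lists had intervals that held 0 at 24 hours. Medians were -0.30 (-0.53 to 0.69) for fibrillar matrix genes, where the collagen gene Col15a1 was at 0.589-fold (0.515 to 0.675), and 0.07 (-0.32 to 0.26) for basement membrane genes. The TGF-beta pathway list had 0.17 (-0.32 to 0.61), with the latent TGF-beta binding gene Ltbp4 at 0.5399-fold (0.503 to 0.5802) and Smad2 at 1.79-fold (1.34 to 2.43), and growth factor receptors had 0.15 (-0.42 to 0.56), with the activin receptor gene Acvr2a at 2.04-fold (1.62 to 2.61). Senescence regulators had a median of 0.40 (-0.55 to 2.92), including the survival gene Bcl2l1 at 1.96-fold (1.53 to 2.55) and Rb1 at 1.800-fold (1.42 to 2.298). Cell cycle genes had a median of 0.13 (-0.24 to 0.29) with no member past 1.5-fold, oxidative stress defence genes 0.00 (-0.22 to 0.56), and dissociation-linked immediate early genes 0.04 (-0.20 to 0.31), with Fosb at 2.35-fold (1.85 to 3.03). A capillary-type cluster with Car4 and Timp4 held the most endothelial-like cells in both libraries, and another cluster was led by Esm1, an endothelial tip-cell gene, and the stress genes Gdf15 and Hspa1a.

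The p53 targets were also higher at 24 hours in the stromal classes, but not in B-like cells. In fibro-adipogenic progenitor-like cells (FAPs) Cdkn1a was 10.1-fold (7.33 to 14.2) higher, Mdm2 4.52-fold (1.93 to 12.9) and Trp53inp1, a p53 cofactor gene, 5.16-fold (2.37 to 13.4). In this list 16 of 18 members were at least 1.5-fold higher and 0 at least 1.5-fold lower (median log2 1.39 (0.94 to 1.83)). Satellite-like cells had Cdkn1a at 20.4-fold (14.2 to 30.5), Ccng1 at 19.4-fold (5.098 to 165) on 2 and 50 UMIs, and Gdf15 with 0 and 64 UMIs, at least 16.6-fold higher. There, 14 of 17 members were at least 1.5-fold higher and 1 at least 1.5-fold lower (median 1.61 (1.07 to 2.97)). In pericyte or smooth muscle-like cells the median was 1.09 (0.71 to 1.71), with Cdkn1a at 6.07-fold (4.53 to 8.32) and Gdf15 at 20.2-fold (6.797 to 98.6). Schwann-like cells had a median of 0.93 (0.42 to 1.53), with Trp53inp1 at 7.16-fold (2.34 to 35.7) and Bax, the pro-apoptotic pore gene, at 2.73-fold (1.77 to 4.41), although Cdkn1a was only 1.904-fold (1.64 to 2.22) higher from a control level of 1052 CPM. A cluster led by Scn7a held 11 of 53 control and 5 of 141 irradiated Schwann-like cells, so ratios of this class at 24 hours include cluster makeup. T-like cells had a median of 0.80 (-0.11 to 1.37), and B-like cells 0.09 (-0.17 to 0.69), with 3 of 12 members at least 1.5-fold higher. FAPs and satellite-like cells had under 50 cells in a library and were described under a lower limit of 25 cells set later.

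Across the other classes at 24 hours, Mdm2 was 6.21-fold (2.82 to 16.1) higher in satellite-like, 2.63-fold (1.54 to 4.84) in pericyte-like and 1.93-fold (0.902 to 4.74) in Schwann-like cells. Ccng1 was 3.25-fold (1.75 to 6.59) higher in FAPs, 4.03-fold (2.29 to 7.72) in pericyte-like and 2.94-fold (1.41 to 7.07) in Schwann-like cells. Phlda3 was 1.84-fold (1.32 to 2.59) higher in FAPs, 3.07-fold (2.18 to 4.39) in satellite-like and 2.43-fold (1.77 to 3.41) in pericyte-like cells, and at 1.09-fold (0.797 to 1.51) in Schwann-like cells. In B-like cells Mdm2 was at 0.888-fold (0.497 to 1.53) and Ccng1 at 0.922-fold (0.424 to 1.89), and Phlda3 had 0 and 6 UMIs. Cdkn1a had 2 and 60 UMIs there, a log2 ratio of 5.50 that was 1.44 once cells with endothelial markers were left out. In T-like cells Cdkn1a had 1 and 30 UMIs, Phlda3 1 and 4, Mdm2 was at 2.65-fold (1.19 to 5.64) and Ccng1 at 1.75-fold (0.876 to 3.32), where 38.2% of irradiated cells held endothelial markers.

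**Figure D2:**
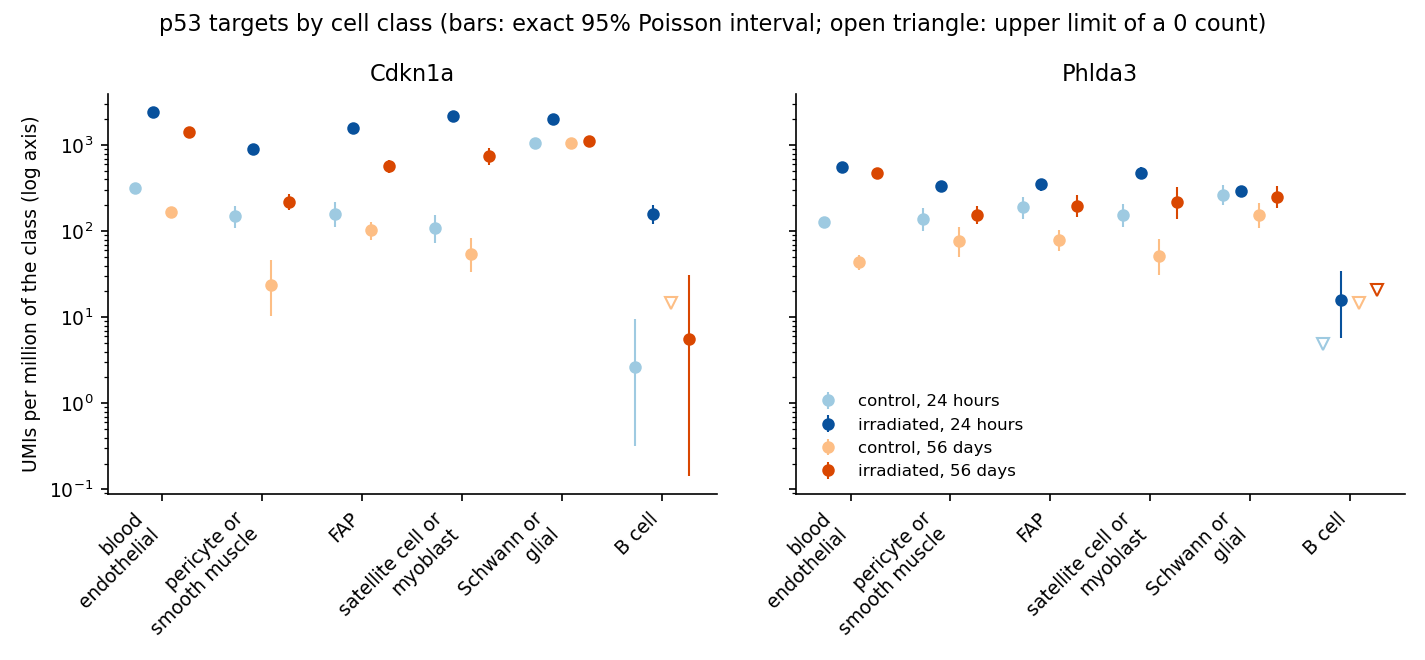
Cdkn1a and Phlda3 in 6 cell classes of the 4 libraries, as CPM on a log axis with exact 95% Poisson intervals. Open triangles mark the upper limit of a 0 count.

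Interferon-response genes, lower in endothelial-like cells at 24 hours, were higher in FAPs, Schwann-like, satellite-like and B-like cells of the same irradiated library, most of them on few UMIs. FAPs had a median log2 ratio of 1.27 (0.17 to 3.62) (6 of 8 members at least 1.5-fold higher), with Ifit2 at 10.7-fold (1.71 to 446), the tetherin gene Bst2 at 1.82-fold (1.27 to 2.65), but log2 -0.089 thinned to 1000 UMIs, and Isg15 on 1 and 29 UMIs, 16.4-fold (2.72 to 669), of which 51.7% lay in 1 cell. The median was 1.76 (0.45 to 2.95) in Schwann-like cells, where Isg15 turned to log2 -0.28 thinned to 1000 UMIs and Ifit3 to -0.35 with cells weighted equally. It was 2.35 (1.54 to 5.32) in satellite-like cells from 4 members (2.33 with the member at 0 set to its bound). In pericyte-like cells it was 0.50 (-0.02 to 1.19), or 0.0596 without cells that held endothelial markers and 1.19 without the top 5% of doublet scores. B-like cells had 0.85 (0.44 to 2.51), with Xaf1 at 5.99-fold (2.85 to 13.7). MHC class I medians at 24 hours were 0.41 (0.11 to 0.71) in FAPs (0.0805 without the top 5% of doublet scores), 0.64 (-0.55 to 1.98) in satellite-like cells, -0.31 (-0.41 to -0.10) in pericyte-like cells (0.67 without the top 5% of doublet scores) and -0.20 (-0.34 to 0.25) in Schwann-like cells. The median over all measured genes at 24 hours was 0.10 in B-like cells, 0.11 in FAPs and Schwann-like cells, 0.12 in T-like cells and myofibre-like barcodes and 0.16 in satellite-like cells, and percentiles already allow for it.

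Immediate early genes and some matrix genes were lower in irradiated FAPs at 24 hours. The elastin gene Eln had 63 and 13 UMIs, a ratio of 0.117-fold (0.0588 to 0.214), and the collagen I genes Col1a1 and Col1a2 were at 0.524-fold (0.494 to 0.555) and 0.558-fold (0.528 to 0.589). The fibrillar matrix list had a median of -0.24 (-0.59 to 0.11), and 2 of 22 members were at least 1.5-fold higher and 6 at least 1.5-fold lower. Dissociation-linked immediate early genes had a median of -0.65 (-1.28 to -0.33), with Fos at 0.4099-fold (0.347 to 0.484) and Jun at 0.487-fold (0.422 to 0.561), beside -0.90 between the control libraries. Gas6 was higher in FAPs at 8.11-fold (5.63 to 12.1) and Igf1, the insulin-like growth factor gene, was at 0.483-fold (0.369 to 0.631) (ligand median 0.17 (-0.91 to 1.49)). Complement genes had a median of -0.58 (-4.53 to 0.77) and the TGF-beta pathway 0.17 (-0.31 to 0.86), with the receptor gene Tgfbr2 at 1.95-fold (1.503 to 2.57). Medians were 0.05 (-0.25 to 0.46) for basement membrane, 0.15 (-1.35 to 0.65) for adipogenic, 0.02 (-0.88 to 0.49) for secretory senescence and -0.08 (-0.42 to 0.60) for oxidative stress defence genes.

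Quiescence genes differed little in satellite-like cells at 24 hours. Pax7, the transcription factor gene that marks satellite cells, was 1.67-fold (1.403 to 2.004) higher in the irradiated library, and the quiescence list had a median of 0.07 (-0.03 to 0.65). Myogenic commitment genes had a median of 0.17 (-1.004 to 1.33), with Myod1 at 0.7096-fold (0.425 to 1.18). Gas6 was 11.9-fold (8.01 to 18.5) and Igf1 1.700-fold (1.25 to 2.33) higher (ligand median 0.78 (-0.38 to 3.55)), while the matrix gene Sparc was at 0.564-fold (0.5100 to 0.624) (matrix median -0.35 (-0.67 to 0.29)). After thinning to 1000 UMIs, no satellite-like cell held an Mki67 or Top2a UMI in either 24-hour library, 0 of 36 and 0 of 75 (1 of 36 and 0 of 78 without thinning), beside 1 of 392 and 0 of 1238 endothelial-like cells.

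In pericyte or smooth muscle-like cells at 24 hours the matrix protease gene Mmp2 had 1 and 177 UMIs, 55.5-fold (9.83 to 2203) higher. Fibrillar matrix genes had a median of 0.15 (-0.09 to 0.39), with the thrombospondin gene Thbs1 at 2.39-fold (1.53 to 3.92) and the proteoglycan gene Bgn at 2.21-fold (1.34 to 3.85). The genes furthest lower were Car4 at 0.0545-fold (0.0137 to 0.1595), the imprinted gene H19 at 0.0922-fold (0.0266 to 0.2603) and Timp4 at 0.213-fold (0.159 to 0.285), of which Car4 and Timp4 are capillary genes. The capillary list had a median of -1.35 (-2.22 to -0.32) in this class. These directions turned with the top 5% of doublet scores removed, a setting that also clustered and named the cells again. Log2 ratios were then 2.21 for Car4 and 2.83 for Timp4, with a list median of 2.41. Without cells that held endothelial markers Timp4 was at 4.59 and the list median at -0.27. Cells with at least 5 UMIs of 9 endothelial markers made up 28.3% and 37.4% of the class in the control and irradiated libraries.

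Myofibre-like barcodes had more Cdkn1a at 24 hours, 10.8-fold (4.81 to 30.3) on 6 and 98 UMIs. Ccng1 was at 1.21-fold (0.883 to 1.66), Phlda3 at 1.31-fold (0.998 to 1.74) and Mdm2 at 0.747-fold (0.256 to 2.22). Malat1, a nuclear RNA, was 73.4-fold (31.3 to 227) higher with 79.2% of its UMIs in 1 barcode, and the actin regulator gene Rflnb had 0 and 20 UMIs, at least 4.43-fold higher. The slow-fibre genes Myl2, Tnnt1 and Tnnc1 had 146, 78 and 55 control UMIs against 0, at least 73.3-fold, at least 39.2-fold and at least 27.6-fold lower.

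Blood and marrow cells formed a smaller share of the irradiated library at 24 hours, 0.270 times the control share (0.233 to 0.312). The ratio of shares was 0.0351 (0.00926 to 0.0946) for erythroid-like cells, 0.119 (0.0614 to 0.215) for marrow progenitor-like cells, 0.198 (0.143 to 0.272) for T-like cells and 0.255 (0.202 to 0.321) for B-like cells. A B precursor-like cluster with Vpreb3, Rag1 and the light chain gene Iglc1 among its leading genes had 56 and 2 cells. Neutrophil-like cells were at 0.688 (0.401 to 1.19), mostly an immature cluster with Ltf, Mmp8 and Ngp in the control and a cluster without them in the irradiated library, and monocyte or macrophage-like cells were at 1.61 (0.916 to 2.97). Within blood and marrow cells alone the ratios were 0.13 (0.0343 to 0.351) for erythroid-like, 0.440 (0.228 to 0.796) for progenitor-like, 0.735 (0.529 to 1.01) for T-like and 0.946 (0.750 to 1.19) for B-like cells. They were above 1 there for neutrophil-like cells, 2.55 (1.49 to 4.43), and macrophage-like cells, 5.97 (3.39 to 11). Cells with an Mki67 or Top2a UMI after thinning to 1000 UMIs were 13 of 31 progenitor-like and 12 of 52 erythroid-like control cells, and 1 of 5 and 0 of 4 irradiated cells.

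Within the B-like class at 24 hours, the genes furthest lower went with its smaller B precursor-like cluster. Il7r, the interleukin 7 receptor gene of B precursors, had 62 UMIs against 0, at least 10.3-fold lower, Sox4 was at 0.102-fold (0.0589 to 0.166) and Atp1b1 at 0.137-fold (0.0798 to 0.2204), or log2 0.34 in the larger B-like cluster alone. The genes furthest higher were the endothelial genes Ptprb (0 and 55 UMIs, at least 36.6-fold), Gng11 (0 and 40 UMIs, at least 26.6-fold) and Nrp1 (0 and 39 UMIs, at least 25.97-fold). Endothelial markers were held by 0.426% and 11.4% of B-like cells in the control and irradiated libraries, and the capillary list had a median of 4.52 (1.54 to 7.05) in B-like cells, with 1 of 6 members at 0 in the control, and 4.21 (0.02 to 5.61) in T-like cells.

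Among stromal and vascular cells at 24 hours, FAPs were at 0.480 times the control share (0.319 to 0.730), satellite-like cells at 0.717 (0.477 to 1.10), pericyte-like cells at 1.16 (0.869 to 1.58), Schwann-like cells at 0.880 (0.637 to 1.23) and endothelial-like cells at 1.05 (0.943 to 1.18).

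At 56 days the p53 targets were still higher in irradiated endothelial-like cells. Phlda3 was 11.03-fold (9.03 to 13.6) higher, Cdkn1a 8.65-fold (7.798 to 9.62) on 412 and 2705 UMIs, Sesn2 9.33-fold (5.08 to 18.8), Mdm2 2.62-fold (2.02 to 3.42) and Ccng1 2.48-fold (1.91 to 3.23). In the list 19 of 23 members were at least 1.5-fold higher and 1 at least 1.5-fold lower, with a median log2 ratio of 1.38 (0.82 to 2.17) at percentile 100.0. Gdf15 was 81.4-fold (34.5 to 253) higher and Ltc4s 34.03-fold (24.2 to 49.5), with 34 and 878 UMIs, so these genes named at 24 hours were again among the largest. The T cell chemokine gene Ccl5 had 0 and 214 UMIs, at least 94.01-fold higher, but 98.6% of them lay in 1 cell. Penk had 122 UMIs against 0 (at least 30.9-fold lower, 87.7% in 1 control cell), Ly6d had 36 against 0 (at least 9.11-fold lower, in 1 control cell), and Klra9 was at 0.02995-fold (0.000742 to 0.176).

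Interferon and antigen-presentation genes, lower in irradiated endothelial-like cells at 24 hours, were higher at 56 days. The interferon list had a median of 0.45 (0.13 to 1.30) at percentile 99.99, and 9 of 19 members were at least 1.5-fold higher and 0 at least 1.5-fold lower. Ifi27l2a was 3.804-fold (3.31 to 4.38) higher, Irf7 3.09-fold (2.55 to 3.76) and Isg15 2.67-fold (2.35 to 3.04). The MHC class I list had a median of 0.33 (0.17 to 0.64), with the heavy chain genes H2-K1 at 1.64-fold (1.57 to 1.71) and H2-D1 at 1.599-fold (1.54 to 1.66) and the light chain gene B2m at 1.53-fold (1.46 to 1.603). At this time the largest endothelial cluster was the capillary-type one with Car4 and Timp4 in the control and one led by Apln, Prnd, Cxcl9 and Ltc4s in the irradiated library, so class ratios include this makeup. The interferon genes Ifit1, Ifit2 and Ifit3 led a further endothelial cluster.

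Matrix genes were higher in irradiated endothelial-like cells at 56 days, and activation and secretory lists had medians above 0 with intervals that held 0. Fibrillar matrix genes had a median of 0.91 (0.02 to 1.27) at percentile 100.0, with Thbs1 at 4.16-fold (2.45 to 7.38), the fibronectin gene Fn1 at 2.42-fold (2.06 to 2.84), Col15a1 at 2.22-fold (1.89 to 2.62) and Sparc at 1.87-fold (1.81 to 1.95). Basement membrane genes had a median of 0.36 (0.18 to 1.31), with Col18a1 at 2.88-fold (2.03 to 4.15) and Nid2 at 2.49-fold (1.81 to 3.44). Activation genes had 0.51 (-0.52 to 1.37), with Apln at 8.27-fold (6.06 to 11.5), the adhesion gene Icam1 at 2.604-fold (1.99 to 3.43) and Angpt2 at 1.805-fold (1.404 to 2.33). The secretory senescence list had 0.60 (-0.32 to 2.31), with the membrane protease gene Mmp14 at 5.27-fold (2.25 to 14.3) and the urokinase receptor gene Plaur at 2.82-fold (1.65 to 4.99). Chemokines had 0.72 (-0.50 to 8.96), with the macrophage growth factor gene Csf1 at 1.86-fold (1.42 to 2.45), and Gas6 was 2.55-fold (2.34 to 2.77) higher in a ligand list of median 0.26 (-0.28 to 0.67).

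Growth factor receptor genes were lower in the same cells, and capillary and break repair lists had medians below 0 with intervals that held 0. Car4 was at 0.194-fold (0.143 to 0.258), Rgcc at 0.5002-fold (0.465 to 0.537) and the fatty acid transporter gene Cd36 at 0.534-fold (0.513 to 0.556) (list median -0.46 (-0.999 to 0.20)). The receptor list had -0.48 (-0.78 to -0.01), with the angiopoietin receptor gene Tek at 0.582-fold (0.518 to 0.653) but Fgfr1 at 3.27-fold (2.02 to 5.43), and the break repair list -0.38 (-0.73 to 0.14), with the kinase gene Prkdc at 0.535-fold (0.326 to 0.857) but the ligase gene Lig4 at 3.39-fold (1.35 to 9.599). Immediate early genes had a median of 0.03 (-0.81 to 0.27), with Fosb at 0.264-fold (0.159 to 0.419) and Jun at 0.571-fold (0.523 to 0.623). Senescence regulators had 0.22 (-0.87 to 3.11), adipogenic genes -0.14 (-0.85 to 0.37), cell cycle genes -0.07 (-0.77 to 0.62), the TGF-beta pathway 0.13 (-0.20 to 0.53) and oxidative stress defence 0.07 (-0.24 to 0.58).

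Irradiated FAPs at 56 days had higher interferon genes. Isg15 was 12.3-fold (6.92 to 23.2) higher, Irf7 11.8-fold (5.995 to 25.2), Ifit3 10.6-fold (5.88 to 20.1) and Bst2 6.37-fold (4.86 to 8.399). In the list 13 of 16 members were at least 1.5-fold higher and 0 at least 1.5-fold lower, with a median log2 ratio of 1.77 (0.89 to 2.76) at percentile 100.0. MHC class I genes had a median of 1.03 (0.56 to 1.67), with Psmb9 at 4.93-fold (2.45 to 10.3) and H2-K1 at 3.19-fold (2.65 to 3.85). The p53 list had 1.08 (0.35 to 1.54), with Cdkn1a at 5.59-fold (4.14 to 7.600), the nuclease gene Aen at 4.08-fold (1.83 to 9.36) and Bax at 2.92-fold (2.03 to 4.22), while Mdm2 was at 0.959-fold (0.397 to 2.101). Phlda3 was 2.55-fold (1.67 to 3.86) higher and Ccng1 was at 1.28-fold (0.663 to 2.36). Gas6 was 3.64-fold (2.86 to 4.65) higher, the BMP-family gene Gdf10 2.82-fold (2.14 to 3.73) (but log2 -0.12 thinned to 1000 UMIs), and Vegfa, the main angiogenic factor gene, was at 0.301-fold (0.116 to 0.654) (ligand median -0.49 (-0.95 to 0.22)).

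More matrix genes were lower than higher in FAPs at 56 days. The fibrillar list had a median of -0.24 (-0.78 to -0.04), and 1 of 22 members were at least 1.5-fold higher and 8 at least 1.5-fold lower, with the fibrillin gene Fbn1 at 0.5399-fold (0.478 to 0.609) and the crosslinking gene Loxl2 at 0.432-fold (0.295 to 0.615) but Bgn at 2.002-fold (1.73 to 2.31), or log2 -0.082 thinned to 1000 UMIs. Basement membrane genes had -0.50 (-1.10 to 0.41), with the laminin genes Lama2 at 0.403-fold (0.312 to 0.515) and Lamc1 at 0.466-fold (0.3704 to 0.5798). Adipogenic genes had a median of 0.64 (0.04 to 1.85) beside a capillary list of 1.85 (0.78 to 5.20) that was 0.87 without the top 5% of doublet scores, and 66.1% of the Fabp4 UMIs lay in 1 cell. Complement genes had 0.34 (-0.22 to 0.98), with C3 at 1.56-fold (1.37 to 1.78), and oxidative stress defence 0.46 (0.12 to 0.98), where 96.9% of Hmox1 UMIs lay in 1 cell. Chemokines had 0.42 (-2.15 to 3.64), secretory senescence genes 0.26 (-1.70 to 1.67), the TGF-beta pathway -0.16 (-0.42 to 0.73) and immediate early genes 0.00 (-0.59 to 0.82).

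Satellite-like cells at 56 days still had more Cdkn1a, 13.7-fold (8.28 to 23.6) on 20 and 78 UMIs, and Phlda3 was 4.24-fold (2.21 to 8.24) higher, with a p53 list median of 0.67 (-1.83 to 3.72). Mdm2 and Ccng1 had few UMIs, 4 and 2 for Mdm2 and 8 and 5 for Ccng1. H2-D1 was 3.18-fold (2.26 to 4.47) and B2m 3.300-fold (1.97 to 5.51) higher (MHC class I median 0.68 (-0.03 to 1.70)). Gas6 was 3.63-fold (2.48 to 5.32) higher and Bmp4, a BMP ligand gene, 3.04-fold (1.73 to 5.32) (ligand median 0.40 (-0.60 to 1.85)). Quiescence genes had a median of 0.10 (-0.55 to 0.62), commitment genes -0.34 (-0.37 to 0.60) and fibrillar matrix genes -0.08 (-0.51 to 0.75). No satellite-like cell held an Mki67 or Top2a UMI after thinning, 0 of 75 and 0 of 26, beside 1 of 634 and 2 of 410 endothelial-like cells.

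Pericyte or smooth muscle-like cells at 56 days had Cdkn1a at 9.23-fold (4.49 to 22.02) and Fst, the follistatin gene, at 5.24-fold (3.17 to 9.15). The neuropeptide gene Gal had 0 and 32 UMIs, at least 8.75-fold higher, all in 1 cell. Rbp7 had 28 UMIs against 0, at least 11.4-fold lower, Igfbp3 was at 0.137-fold (0.0471 to 0.328) and the ribosomal RNA-derived transcript AY036118 at 0.282-fold (0.258 to 0.308). The p53 list had a median of 0.27 (-0.59 to 0.89), or 1.29 thinned to 1000 UMIs, with Bax at 2.93-fold (1.98 to 4.46) and Plk2 at 0.112-fold (0.0214 to 0.372). Phlda3 was 2.02-fold (1.26 to 3.32) higher, Ccng1 was at 1.46-fold (0.607 to 3.74) and Mdm2 at 0.969-fold (0.401 to 2.39). Capillary genes had -0.83 (-0.95 to -0.01), or 0.20 without cells that held endothelial markers. Interferon genes had 1.13 (0.49 to 1.84), with Isg15 at 3.64-fold (2.296 to 5.99), Ifi27l2a at 3.302-fold (2.302 to 4.84) and Bst2 at 2.34-fold (1.68 to 3.31), and the median was 2.38 without cells that held endothelial markers. MHC class I genes had 0.39 (0.19 to 0.76), which reversed to -0.088 at no more than 10% mitochondrial UMIs. Fibrillar matrix genes had 0.38 (0.20 to 0.65), with Eln at 3.21-fold (2.29 to 4.57) and Bgn at 2.31-fold (1.53 to 3.57), and oxidative stress defence genes 0.67 (0.27 to 1.05), with Gclm at 2.68-fold (1.34 to 5.85) and Gpx1 at 1.97-fold (1.49 to 2.62).

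Schwann-like cells at 56 days had higher MHC class I genes. H2-D1 was 4.28-fold (3.42 to 5.403), H2-K1 3.83-fold (2.69 to 5.55) and B2m 2.62-fold (1.98 to 3.47) higher. In the list 8 of 9 members were at least 1.5-fold higher and 0 at least 1.5-fold lower, with a median log2 ratio of 1.92 (1.03 to 2.09) at percentile 100.0. Interferon genes had a median of 1.23 (-0.73 to 3.71), with Ifi27l2a at 14.1-fold (6.52 to 36.3). Cdkn1a was at 1.06-fold (0.875 to 1.28), Phlda3 at 1.64-fold (1.04 to 2.595) and Ccng1 at 0.8101-fold (0.291 to 2.11), with 9 and 3 UMIs of Mdm2 and a p53 list median of 0.35 (-0.07 to 0.76). The ectonucleotidase gene Entpd2 was 47.4-fold (7.98 to 1923) higher on 1 and 36 UMIs, the heat shock gene Hspb1 had 0 and 23 UMIs (at least 10.1-fold higher), and Aqp1 was 32.3-fold (8.46 to 274) with 95.9% of UMIs in 1 cell. AY036118 was at 0.173-fold (0.143 to 0.209), Cep85l at 0.123-fold (0.0242 to 0.395), and Cxcl14 had 21 UMIs against 0 (at least 5.32-fold lower). Entpd2 was at 0.0448-fold (0.0115 to 0.127) at 24 hours. The class held a cluster led by Scn7a, Cdh19 and Aspa, so its ratios, Entpd2 among them, include cluster makeup, and MHC class I genes were not compared within clusters.

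Irradiated macrophage-like cells at 56 days had more antigen-presentation RNA and less monocyte RNA. Cd74, the invariant chain gene, was 2.26-fold (2.16 to 2.38) and H2-Aa 2.29-fold (2.13 to 2.47) higher (MHC class II median 1.18 (0.21 to 1.24)). Monocyte-derived genes had a median of -1.28 (-2.69 to -0.61), with Ly6c2 at 0.152-fold (0.0935 to 0.237), Hp at 0.249-fold (0.152 to 0.392) and Plac8 at 0.447-fold (0.384 to 0.5205), and 0 of 8 members were at least 1.5-fold higher and 8 at least 1.5-fold lower. Resident genes had -0.60 (-1.41 to -0.33), with the scavenger receptor gene Cd163 at 0.373-fold (0.269 to 0.512) and F13a1 at 0.546-fold (0.472 to 0.632), but the median was -0.22 without cells that held endothelial markers. Among lipid and repair genes (median 0.30 (-1.05 to 3.07)), the lipase gene Lpl was 8.51-fold (6.19 to 11.96) and Ctsd 1.95-fold (1.54 to 2.49) higher. Medians were 0.28 (0.06 to 0.49) for MHC class I, -0.09 (-0.80 to 0.19) for interferon and 0.10 (-0.68 to 0.68) for p53 genes, over an all-gene median of -0.11. Cdkn1a was 1.66-fold (1.18 to 2.34) higher, Mdm2 was at 1.62-fold (0.776 to 3.53), Ccng1 at 0.954-fold (0.482 to 1.88) and Phlda3 had 1 and 10 UMIs. Most control cells came from a cluster with Ccr2 and Plac8 (32 of 54) and most irradiated cells from a cluster with C1qa, Mrc1 and Folr2 (27 of 48), and the class had under 50 cells in the irradiated library.

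The genes furthest higher in B-like cells at 56 days included the glycolytic genes Gapdh at 4.43-fold (2.52 to 8.16) and Gpi1 at 3.34-fold (1.85 to 6.29), beside the selenoprotein gene Selenow at 2.56-fold (1.88 to 3.51). Jchain, the immunoglobulin joining chain gene of plasma cells, had 1691 and 1 UMIs, with 97.3% of control UMIs in 1 cell, Slpi had 87 UMIs against 0 (at least 20.4-fold lower, in 2 cells) and Apoe was at 0.1303-fold (0.0608 to 0.249). The p53 list had a median of 0.09 (-2.58 to 0.56) from 5 members and the interferon list 0.47 (-1.23 to 0.73) from 4. Cdkn1a had 0 and 1 UMIs, Mdm2 7 and 11 and Ccng1 6 and 7, and Phlda3 was not seen.

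**Figure D3:**
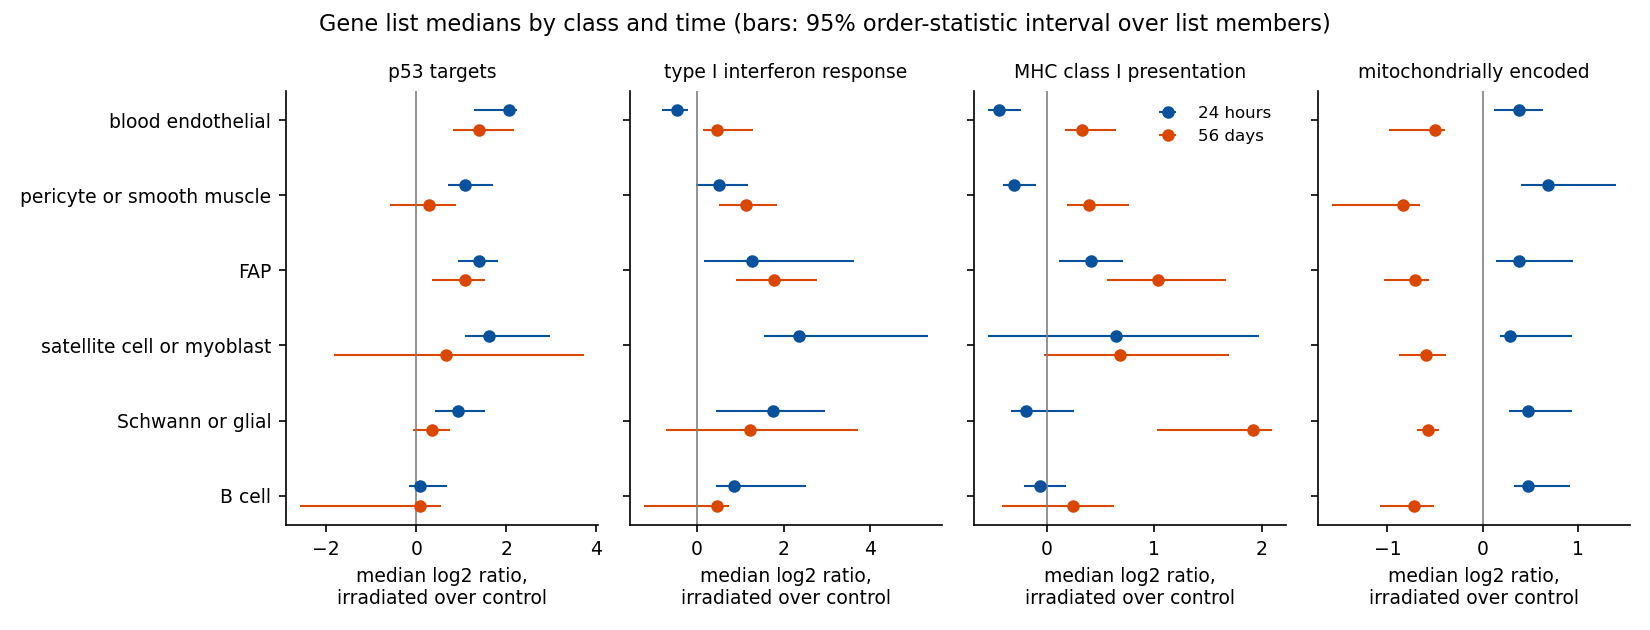
Median log2 ratio of irradiated over control for p53, interferon, MHC class I and mitochondrially encoded genes in 6 cell classes at 24 hours (blue) and 56 days (orange). Bars show 95% order-statistic intervals of the median, or the range where a list has under 6 members.

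Mitochondrially encoded genes were higher in the irradiated library in every described class at 24 hours. Medians were 0.37 (0.12 to 0.63) in endothelial-like cells, led by mt-Nd6 at 4.28-fold (3.37 to 5.52) and mt-Nd4l at 2.01-fold (1.88 to 2.15). They were 0.38 (0.14 to 0.94) in FAPs, 0.28 (0.18 to 0.93) in satellite-like, 0.68 (0.40 to 1.39) in pericyte-like, 0.47 (0.27 to 0.93) in Schwann-like, 0.47 (0.32 to 0.91) in B-like and 0.54 (0.34 to 1.12) in T-like cells, and 0.68 (0.50 to 0.77) in myofibre-like barcodes. At 56 days the same genes were lower in every described class but myofibre-like barcodes, with -0.50 (-0.99 to -0.39) in endothelial-like cells (mt-Nd6 at 0.337-fold (0.263 to 0.429)). They were -0.72 (-1.04 to -0.56) in FAPs, -0.60 (-0.88 to -0.38) in satellite-like, -0.84 (-1.58 to -0.66) in pericyte-like, -0.57 (-0.69 to -0.46) in Schwann-like, -0.72 (-1.07 to -0.52) in B-like and -0.75 (-1.45 to -0.48) in macrophage-like cells. In myofibre-like barcodes the median was 0.13 (-0.37 to 0.54), from 11 members. The median mitochondrial share per kept cell was 3.07%, 3.99%, 3.44% and 2.72% in the 4 libraries.

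Blood and marrow shares were mostly nearer to the control at 56 days than at 24 hours. These cells together were at 0.677 times the control share (0.570 to 0.802), neutrophil-like cells at 0.1803 (0.111 to 0.280), erythroid-like cells at 0.597 (0.387 to 0.900) and progenitor-like cells at 0.686 (0.374 to 1.21). T-like cells were at 0.935 (0.343 to 2.35), while B-like cells were at 1.50 (1.04 to 2.15), their B precursor-like cluster at 2.48 (1.28 to 4.91), and macrophage-like cells at 1.56 (1.03 to 2.34). Among stromal and vascular cells, FAPs were at 0.588 (0.391 to 0.867), satellite-like cells at 0.549 (0.340 to 0.862), pericyte-like cells at 1.80 (1.28 to 2.54) and Schwann-like cells at 1.40 (0.965 to 2.04). Cells with an Mki67 or Top2a UMI were 26 of 44 progenitor-like and 57 of 89 erythroid-like control cells and 10 of 18 and 16 of 29 irradiated cells.

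The control libraries also differed from each other, in a contrast that holds age, animals and day together. It is a rough background only, and does not measure the spread between limbs of the same mice. Between CON 56 days and CON 24 hours, the share ratio was 6.48 (4.30 to 10.1) for neutrophil-like, 0.231 (0.174 to 0.303) for B-like, 0.0809 (0.0441 to 0.138) for T-like and 0.711 for blood and marrow cells. Among stromal and vascular cells it was 1.39 (0.956 to 2.04) for FAPs and 0.668 (0.463 to 0.963) for pericyte-like cells. The p53 list had a median of -0.60 (-0.87 to -0.12) in endothelial-like, -0.59 (-0.94 to 0.39) in pericyte-like, -0.41 (-0.97 to 0.58) in satellite-like cells and -0.01 (-0.63 to 0.74) in FAPs. The interferon list had -0.06 (-0.35 to 0.19) in endothelial-like cells and 0.73 (-0.43 to 1.95) in FAPs, and mitochondrially encoded genes had 0.28 (0.15 to 0.87) and 0.43 (0.06 to 1.16). Haemoglobin Hba-a1 had 9674, 677.8, 7527 and 5336 CPM in the 4 libraries, and the muscle actin gene Acta1 had 2858, 2326, 625.4 and 1133. Both can reach droplets of other classes as ambient RNA, which was not removed.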

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

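The direction of several results differed between 24 hours and 56 days, and none of these differences was tested. All explanations weighed here, and their tests, were chosen after the data were seen. The share ratio of B-like cells among kept cells was 0.255 at 24 hours and 1.50 at 56 days, a ratio of ratios of 5.87. Within blood and marrow cells it was 0.946 (0.750 to 1.19) and then 2.21, so the lower value at 24 hours held for 1 denominator only. B-like cells made up 17.6% and 4.50% of kept cells in the control and irradiated libraries at 24 hours, and 4.08% and 6.11% at 56 days. Between the controls, 56 days over 24 hours, the ratio was 0.231 among kept cells and 0.325 within blood and marrow cells. The change of direction therefore includes the difference between the control libraries. The interferon median in endothelial-like cells was -0.46 and then 0.45, a difference of 0.92 in log2, and the MHC class I median differed by 0.78 in endothelial-like cells (-0.45, then 0.33) and by 0.70 in pericyte-like cells (-0.31, then 0.39). Both pericyte values reverse with other settings, to 0.67 without the top 5% of doublet scores at 24 hours and to -0.088 at no more than 10% mitochondrial UMIs at 56 days. Both settings also clustered and named the cells again. Mitochondrially encoded genes differed by -0.88 in endothelial-like cells (0.37, then -0.50), -1.10 in FAPs (0.38, then -0.72), -0.88 in satellite-like cells (0.28, then -0.60), -1.51 in pericyte-like cells (0.68, then -0.84), -1.04 in Schwann-like cells (0.47, then -0.57), -1.19 in B-like cells (0.47, then -0.72) and -0.55 in myofibre-like barcodes (0.68, then 0.13).

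Mitochondrially encoded genes may differ through library-wide RNA quality or handling rather than through irradiation of a cell type. B-like cells, whose p53 list medians were 0.09 at both times, had a mitochondrial median of 0.47 (0.32 to 0.91) at 24 hours and -0.72 (-1.07 to -0.52) at 56 days. A library-wide difference would give this direction in every class, but myofibre-like barcodes, which had few UMIs, were at 0.13 (-0.37 to 0.54) at 56 days, so the explanation stays open. More damaged cells among those kept, if they lay over 10% mitochondrial UMIs, would give a median near 0 once such cells were left out. The endothelial median at 24 hours was then 0.35, inside the interval of the main median (0.12 to 0.63). Cells over 10% therefore did not account for the difference. The median share of kept cells in that irradiated library was 3.99%, so damaged cells under 10% stayed in and their part stays open. Separate libraries prepared from each limb would tell handling from biology.

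Blood and marrow classes were rare in the irradiated library at 24 hours, which could come from carry-over of less marrow and blood. If every class were lower by 1 factor, the cell number ratio of erythroid and progenitor classes over neutrophils and macrophages would be near 1. It was 0.0747 (0.0377 to 0.142), and the same ratio between the 2 controls, which also differ in age, animals and day, was 0.185 (0.120 to 0.280). With 1 library per group and no like-for-like background, carry-over by 1 factor cannot be told apart from other differences between libraries. A single factor for marrow classes would make the erythroid over progenitor ratio near 1, and at 0.298 (0.0675 to 1.02), against 2.11 between the controls, that cannot be told apart from unequal loss. Loss of dividing marrow cells after irradiation would put erythroid and progenitor cells below B and T cells only if it spared the latter. The ratio was 0.333 (0.185 to 0.571), against 5.19 between the controls. The B-like class was no spared reference, since its B precursor-like cluster had 56 and 2 cells. Unequal carry-over of marrow against blood would also give a ratio under 1, so these cannot be told apart. Counts of marrow and blood cells per limb would settle it.

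Clock output genes were higher in the irradiated library at 24 hours, which might reflect limbs of the same mice processed at another time of day. That would put every measured output gene higher in satellite-like cells too, whose median was 0.75 (range of 5 genes -0.15 to 1.68), so a time-of-day difference and a cell-type response cannot be told apart. Endothelial RNA, if confined to cells that held endothelial markers, would leave no difference in the other pericyte-like cells. The median there was 1.73 (range of 5 genes 0.25 to 5.44), against 2.53 with all cells, so the difference did not disappear. Dbp, Nr1d1 and Nr1d2 had lower ratios without those cells, and Tef and Per3 higher ones, on control counts of 0 to 10 UMIs. These counts do not show what part went with mixed cells. Ambient endothelial RNA may remain in the other droplets, so its part stays open.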

How the results depend on the processing

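Settings for removal of high doublet scores, endothelial-marker cells and the larger B-like cluster were chosen after the data were seen, and the others before. A value counted as reversed only if its direction turned and the main interval excluded no difference. Other changes of sign were counted as stayed or moved. Of 1858 alternative values of 120 list medians, 1801 stayed inside the main interval, 53 moved outside it and 4 reversed, and 1762 kept their sign. Without endothelial-marker cells, for example, the p53 median was -0.285 against 0.098 in macrophage-like cells at 56 days, and -0.27 against 0.09 in B-like cells at 24 hours. Of 4828 values of 351 gene ratios, 4461 stayed, 344 moved and 23 reversed. Thinning to 1000 UMIs gave 114 of those moved and 8 of those reversed, from 347 values, and scaling by TMM moved 6 of 350. Of 191 values of 28 share ratios 181 stayed and 10 moved, and of 32 values of 16 cycling shares 22 stayed and 10 moved. With no cell filter the blood and marrow ratio at 24 hours was 0.314 against 0.270. Thinned to 1000 UMIs, the p53 median at 56 days was 1.60 against 1.08 in FAPs and 1.29 against 0.27 in pericyte-like cells. The cause was not tested. No paired analysis was possible because limbs were pooled. Depth limits genes with few UMIs, so small classes were described for fewer genes.

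Reversed values, in log2, were as follows. With the top 5% of doublet scores removed, pericyte-like cells at 24 hours had an MHC class I median of 0.67 against -0.31 and a capillary median of 2.41 against -1.35, with B2m 0.69, Car4 2.21, H2-D1 1.13, H2-Q4 2.31 and Timp4 2.83, and FAPs at 56 days had Hmox1 -0.11. Without endothelial-marker cells, pericyte-like cells had B2m 0.0599, H2-Q4 0.15 and Timp4 4.59 at 24 hours, and a capillary median of 0.20 against -0.83 and Fabp4 0.20 at 56 days, where Aqp1 was -0.60 in FAPs and Rps27l -0.058 in macrophage-like cells. At most 10% mitochondrial UMIs gave pericyte-like cells at 56 days an MHC class I median of -0.088 against 0.39 and H2-D1 -0.096. Thinned to 1000 UMIs, Bst2 was -0.089 and Psmb10 -0.60 in FAPs and Isg15 -0.28 in Schwann-like cells at 24 hours, and at 56 days Bgn was -0.082, Cfb -0.45 and Gdf10 -0.12 in FAPs, Irf7 -0.15 in macrophage-like cells and Psmb10 -0.13 in pericyte-like cells. Weighting cells equally gave Ifit3 -0.35 in Schwann-like cells at 24 hours, and the larger B-like cluster alone gave Atp1b1 0.34 at 24 hours.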

Other observations

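Genes of the circadian clock, chosen after their ratios were seen, differed between the 24-hour libraries. In endothelial-like cells 7 of 7 output genes were higher in the irradiated library, with a median log2 ratio of 1.69. Dbp, a clock-controlled transcription factor gene, was 4.39-fold (3.57 to 5.46) higher, its relative Tef 3.55-fold (2.75 to 4.66), Per3 3.05-fold (2.28 to 4.17) and the repressor gene Nr1d1 2.03-fold (1.66 to 2.51). Arntl, the core activator gene that peaks in the opposite phase, was at 0.228-fold (0.131 to 0.392). The median was 2.53 in pericyte-like cells, 2.36 in FAPs, 1.05 in Schwann-like cells and 0.75 in satellite-like cells, in which Dbp was at 1.05-fold (0.645 to 1.73). At 56 days it was 0.63 in endothelial-like cells, -0.83 in FAPs and 0.06 in satellite-like cells.

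The doublet-score and endothelial-marker settings named here were chosen after the data were seen, and thinning before. The p53 medians of endothelial-like cells stayed inside their intervals under every setting tried, but values in pericyte-like cells were less certain. Their p53 median at 56 days was 0.27 and became 1.29 when each cell was thinned to 1000 UMIs. Thinning left out cells under 1000 UMIs and lowered summed UMIs, so the 2 medians may rest on different list members. The cause of the difference was not tested. The MHC class I median of pericyte-like cells at 24 hours, -0.31 with all cells, became 0.67 without the top 5% of doublet scores. It stayed at -0.32 without cells that held endothelial markers. The first setting also clustered and named the cells again, so class membership may differ, which leaves the part of mixed cells open. Sorting of pericytes with a surface marker in replicate animals would settle this.

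The higher MHC class I genes of irradiated FAPs, Schwann-like and endothelial-like cells at 56 days, and the higher interferon genes of FAPs and endothelial-like cells, could reflect an inflammatory response. The Schwann-like interferon median had an interval that spanned no difference, and was 0.98 without cells that held endothelial markers. A cluster led by Scn7a held 3 of 63 control and 14 of 58 irradiated Schwann-like cells at 56 days, and 11 of 53 and 5 of 141 at 24 hours. Cluster makeup may therefore bear on their medians at both times. The interferon median changed sign in endothelial-like cells, from -0.46 at 24 hours to 0.45 at 56 days. It was already above 0 at 24 hours in FAPs (1.27, then 1.77), pericyte-like cells (0.50, then 1.13) and Schwann-like cells (1.76, then 1.23). The pericyte-like interval at 24 hours spanned no difference. That median was 0.0596 without cells that held endothelial markers and 1.19 without the top 5% of doublet scores. Differences between the times were not tested. The MHC class I median at 56 days was 1.02 in FAPs and 1.80 in Schwann-like cells without the top 5% of doublet scores, and 0.997 and 1.72 without cells that held endothelial markers. With 1 library per group the higher genes might still come from a difference between pools, and the shielded limb of the same mice may itself have responded to factors in the blood, which these data did not test. Repeats in separate mice with limbs of unirradiated mice would address both.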
